A study of Homo sapiens with 16 samples.

How the data were processed

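Gene expression was measured on 16 Illumina expression bead arrays, each hybridized with biotin-labelled complementary RNA from HT-29 cells, an established human colon adenocarcinoma line. The cells carried a doxycycline-inducible cassette (TetTight) for GATA6L, the long isoform of the transcription factor GATA6. All received interferon-gamma at 200 U/ml for 24 h, with doxycycline at 0 or 1 µg/ml over the same 24 h, and then tumour necrosis factor (TNF) at 0 or 100 ng/ml for 2 h. The labels give 4 groups of 4 replicates each, while the series text speaks of biological triplicate. The origin of the replicates is not given in the sources used here beyond their numbers, so the p-values measure the spread between these samples.

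The deposited table without normalization holds, for each probe and array, the mean bead signal as an intensity, a detection p-value, the number of beads and a bead standard error. The authors' normalized table is on the log2 scale and was made with lumi, per the submitters' processing notes; its version and settings are not given in the sources used here. The deposited detection p-value is the share of negative control probes at least as bright, and its smallest step of 0.0013 implies 770 such probes. The deposited series values were checked and are identical to the authors' log2 table (largest difference 0), and within every array the authors' values keep the rank order of the intensities (lowest Spearman rho 1, lowest Pearson r with log2 intensity 0.997). The 16 columns of bead standard errors were not used.

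The table has 47231 probes. They were given gene names from the files' own annotation and a RefSeq gene table: 27384 through an accession whose gene carries the file's symbol as its name or synonym, or whose kind of transcript matches the probe's definition, 3481 through a current symbol and 1417 through an unambiguous older symbol. For 11679 probes the file's symbol was kept, and 3270 have none. For 54 probes a symbol that had turned into a date was restored from the definition. The result is 30744 distinct genes, of which 8779 have at least 2 probes, and 5264 probes carry a name that differs from the file's symbol. The naming was revised once after misnamed probes were seen. No coordinates were used, since the genome build of the probes is not given in the sources used here.

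Intensities were background corrected by normexp with an offset of 16, its parameters inferred from the detection p-values, then quantile normalized and put on the log2 scale with limma 3.58.1 in R 4.3.3. Probes with a detection p under 0.05 on at least 4 of the 16 arrays were kept, which left 20108. A gene was represented by its probe with the highest mean, which gave 15664 features, 1279 of them probes without a gene symbol that were counted and not named. limma's lmFit with a mean for each of the 4 groups and eBayes without an intensity trend (12 residual and 6.46 prior degrees of freedom) gave 5 comparisons: TNF against none without and with doxycycline, doxycycline against none without and with TNF, and their interaction. The groups share one estimate of the spread, since all arrays are of one platform and one line. P-values were adjusted by Benjamini-Hochberg over all features, and a gene was called at an adjusted p under 0.05. For arrays the number of arrays limits the precision.

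Of 24 fixed gene lists, 23 have at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. The lists are NF-kB targets and feedback, chemokines and cytokines, AP-1 and immediate early genes, interferon-gamma response, antigen presentation, type I interferon response, cell death and survival, GATA and endoderm transcription factors, enterocyte genes, goblet and other secretory lineage genes, intestinal stem cell and Wnt target genes, cell cycle, integrated stress response, nuclear-encoded oxidative phosphorylation, mitochondrial ribosome and proteostasis, glycolysis and hypoxia, cholesterol and fatty acid synthesis, insulin and growth factor signalling, TGF-beta and BMP signalling, epithelial junctions and keratins, protein folding and heat shock, metallothioneins and metal response, fibroblast markers and blood cell markers. The size of the TNF response was compared with fry on the interaction, over the genes called in the mean TNF effect of both doxycycline states, each gene signed by that effect, and the p-values of each such family of fry tests were adjusted by Benjamini-Hochberg, a step added after their values were known. Fry tests whether a set moves on balance one way and does not compare it with other genes.

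Comparisons, lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule names GATA6 in every comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose 4 values in one group all lie above or all below the 4 of the other (for the interaction, the 8 of each sign with the smallest adjusted p), and up to 3 members of each list with the smallest p, of which the text gives those its gene groups need. Any member of a fixed list could also be named with its value.

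The alternatives were the authors' values, the series values, no background correction, an offset of 50, scaling to the 75th percentile in place of quantile normalization, no detection filter, a stricter filter (detection p under 0.01 on at least 8 arrays), the mean or the most variable probe of a gene, an intensity trend, array weights, a fit of only the groups compared, the replicate number as a block, each array left out in turn, an adjusted p under 0.01 or a 2-fold minimum for counts, the estimated correlation and fry for lists, and another choice of genes for the response size. A slide block was not run, since the files name no slides.

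On simulated data with the real genes' means and spreads, the TNF comparison without doxycycline on 15664 genes recovered 65% of 100 genes changed by 0.5 and 100% of 100 changed by 1 on the log2 scale, with 4.62% of its 173 calls false. For doxycycline without TNF, a simulated shift of -0.3 in the antigen presentation list was called (adjusted p = 5.03e-25) and 0 of the other lists. In simulated data without an interaction, 49.9% of rising genes and 50% of falling genes responded less with doxycycline (limma fry, adjusted p = 0.705 and adjusted p = 0.422). These data gave 0 interaction calls over 15664 genes. In all simulations the noise was drawn independently for each gene on the final log2 scale. Correlation between genes, background, normalization and the detection floor were not simulated. The simulations therefore cannot show whether these bias the response size or the list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.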

Results

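Transcript levels were measured in HT-29 cells with a doxycycline-inducible GATA6L cassette, all treated with interferon-gamma for 24 h. The groups were cells without doxycycline or TNF, with TNF for 2 h, with doxycycline for 24 h, and with doxycycline followed by TNF, with 4 arrays each. The median signal per array lay between 84.5 and 99.4, the probes detected between 17139 and 18864 (36.3% to 39.9%), and the mean number of beads per probe between 20.1 and 21.9. The first principal component of the 15664 genes and unnamed probes tested held 34.4% of the variance and the second 23.5%.

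**Figure D1:**
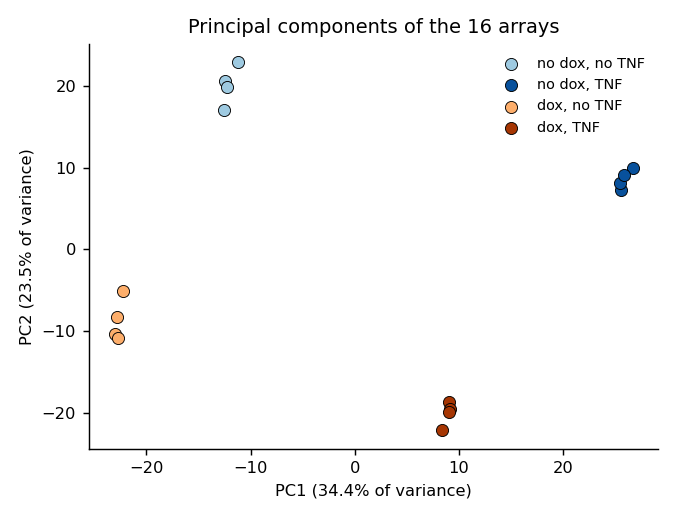
First and second principal component scores of the 16 arrays, 1 point per array, coloured by group. The axes hold 34.4% and 23.5% of the variance.

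The first comparison asks which transcripts responded to TNF in cells without doxycycline. CCL20 rose 129-fold (log2 fold change 7.01, SE 0.10, adjusted p = 5.65e-20, higher in 4 of 4 arrays) and CXCL8 rose 82.6-fold (6.37, SE 0.08, adjusted p = 1.24e-20), followed by PTGS2 at 23.2-fold, CXCL2 at 21.4-fold and PI3 at 20.4-fold. TNF itself rose (adjusted p = 1.48e-18) from a group in which its probe was not detected on any array, so its fold is not given; over the alternatives its log2 change lay between 2.35 and 4.29. The feedback genes NFKBIA (10-fold) and BCL3 (7.91-fold) rose as well, as did TNFAIP3 (adjusted p = 3.34e-17), whose probe was detected on 1 of 4 arrays without TNF and whose log2 change lay between 2.6 and 4.49 over the alternatives. Among genes that fell, AXIN2 fell by 2.69 on the log2 scale (adjusted p = 5.83e-14, lower in 4 of 4 arrays), PRR15L fell by 2.46, ENC1 fell by 1.87, BMP4 fell by 1.75, RNF43 fell by 1.68, CEBPA fell by 1.60, BDNF fell by 1.57 and PRAG1 fell by 1.55. SLC25A24 rose 19.2-fold on the probe used, while its other probes gave log2 changes of -0.33 and 0.16 that did not pass the test. The sizes depended on the processing: without background correction CCL20 rose 42.8-fold, CXCL8 54.9-fold, PI3 11-fold, CXCL2 9.51-fold, PTGS2 8.75-fold, SLC25A24 7.31-fold and BCL3 5.58-fold, AXIN2 fell by 1.9, PRR15L fell by 1.76, RNF43 fell by 0.945, PRAG1 fell by 0.852, CEBPA fell by 0.636 and BDNF fell by 0.609, and each kept its direction and call. Over the 192 gene results of all comparisons, the median size without background correction was 0.736 of the main one on the log2 scale.

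In all, 772 genes rose and 750 fell, 202 and 40 of them by at least 2-fold. For 1398 of these 1522 genes the 4 values of one group lay entirely above or below those of the other, which calling on the same values favours. Over all features tested the share was 14.2%, against 2.86% by chance. Camera called 8 of 23 lists. Of the NF-kB targets 25 of 29 rose and 0 fell (26 and 1 adjusted over the list alone), of the chemokines and cytokines 21 of 26 (21 adjusted over the list alone), and of the AP-1 and immediate early genes 20 of 27 with 1 lower (20 and 2 adjusted over the list alone), among them DUSP5 (7.04-fold), FOSB (7-fold) and PPP1R15A (5.18-fold). In the interferon-gamma response list 12 of 29 rose and 1 fell (12 and 2 adjusted over the list alone), led by ICAM1 (6.08-fold) and UBD (6.05-fold). These 4 lists held with an estimated correlation. Antigen presentation was called upward with 2 of 23 genes higher (2 adjusted over the list alone), among them HLA-DRA (1.35-fold), but adjusted p = 0.0687 with an estimated correlation. Cell death and survival genes were called upward with 4 of 28 higher and 1 lower (5 and 1 adjusted over the list alone), including BBC3 (3.79-fold), TNFRSF10B (2.96-fold) and PMAIP1 (2.5-fold), but adjusted p = 0.0798 with an estimated correlation. The intestinal stem cell and Wnt target list was called downward with 6 of 15 lower and 1 higher (8 and 1 adjusted over the list alone), including DKK1 (fell by 1.02), but adjusted p = 0.0687 with an estimated correlation. The cell cycle list was called downward with 3 of 30 lower (5 adjusted over the list alone), but adjusted p = 0.0768 with an estimated correlation. Outside the called lists, MUC5AC rose 3.68-fold, FOXO1 3.05-fold, SOX9 2.16-fold and ELF3 1.8-fold, while TGFBR2 fell by 0.99 and PDX1 fell by 0.91. Without background correction DUSP5 rose 4.5-fold, FOSB 3.12-fold, MUC5AC 2.48-fold and BBC3 2.31-fold, and PDX1 fell by 0.386.

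The second comparison asks the same question in cells with doxycycline. CCL20 rose 96.6-fold (log2 fold change 6.59, SE 0.10, adjusted p = 1.75e-19, higher in 4 of 4 arrays) and CXCL8 78.7-fold, followed by CXCL1 (23.3-fold), PI3 (15.4-fold), CXCL2 (15.3-fold), CX3CL1 (15.1-fold), CDKN1A (14.8-fold) and SDC4 (14.6-fold). TNFAIP3 rose 11.1-fold, PTGS2 9.44-fold, BCL3 7.23-fold and NFKBIA 6.56-fold. TNF rose as well (adjusted p = 8.06e-17), again from a group without a detected array, with a log2 change between 1.7 and 3.41 over the alternatives. AXIN2 fell by 2.12 (adjusted p = 3.07e-12, lower in 4 of 4 arrays), PRR15L fell by 1.73, BMP4 fell by 1.42, RTL10 fell by 1.25, B4GAT1 fell by 1.19, LOC730525 fell by 1.12, PIM1 fell by 1.10 and RNF43 fell by 1.09. Without background correction CCL20 rose 31.6-fold, CXCL8 40.8-fold, CX3CL1 11-fold, SDC4 10.8-fold, CXCL1 9.06-fold, CDKN1A 8.4-fold, PI3 7.01-fold, CXCL2 6.19-fold, TNFAIP3 3.78-fold and PTGS2 3.36-fold, AXIN2 fell by 1.19, B4GAT1 fell by 0.713, RTL10 fell by 0.568, PIM1 fell by 0.497, and LOC730525 and RNF43 each fell by 0.475.

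Here 604 genes rose and 472 fell, 156 and 15 of them by at least 2-fold. Groups did not overlap for 1016 of the 1076, and for 12.6% of all features tested. Of the genes that rose without doxycycline, 465 also rose here, where 29.8 would be shared by independent sets, and 297 fell in both, against 22.6. Across 15664 genes, which are not independent replicates, the fold changes correlated with Pearson's r of 0.785 and Spearman's rho of 0.447. Camera again called 8 of 23 lists, with 5 called without PlusGATA6L_NoTNF replicate 2 and 5 without PlusGATA6L_PlusTNF replicate 4. NF-kB targets rose in 23 of 29 genes (24 adjusted over the list alone), chemokines and cytokines in 17 of 26 (20 adjusted over the list alone), AP-1 and immediate early genes in 22 of 27 (24 adjusted over the list alone) with DUSP5 (6.76-fold) and FOSB (4.76-fold), and interferon-gamma response genes in 10 of 29 with 1 lower (14 and 2 adjusted over the list alone), led by UBD (6.24-fold) and ICAM1 (5.89-fold). Antigen presentation was called upward with 3 of 23 higher (5 adjusted over the list alone), and adjusted p = 0.0493 with an estimated correlation; CD74 rose 1.35-fold, with another of its probes at 0.09 on the log2 scale and not called. Cell death and survival genes were called upward with 4 of 28 higher and 2 lower (5 and 2 adjusted over the list alone), including BBC3 (3.77-fold), but adjusted p = 0.155 with an estimated correlation. The stem cell and Wnt target list was called downward with 4 of 15 lower and 0 higher (7 and 1 adjusted over the list alone), but adjusted p = 0.155 with an estimated correlation. The cell cycle list was called downward with 1 of 30 lower (1 adjusted over the list alone), but adjusted p = 0.155 with an estimated correlation. FOXO1 rose 4.74-fold, SOX9 2.98-fold, MUC5AC 2.77-fold and ELF3 2.4-fold, and PDX1 fell by 0.93. Without background correction DUSP5 rose 3.89-fold, FOXO1 2.91-fold, FOSB 2.48-fold, BBC3 2.38-fold and MUC5AC 1.78-fold, and PDX1 fell by 0.392.

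The third comparison asks what 24 h of doxycycline changed in cells without TNF. Since no doxycycline-treated cells without the cassette were among the samples, the drug and the transgene cannot be separated. LXN rose 8.42-fold (log2 fold change 3.07, SE 0.08, adjusted p = 2.05e-14, higher in 4 of 4 arrays), MB21D2 5.38-fold, the TNF receptor gene TNFRSF1B 3.96-fold, LYN 3.76-fold, NDRG1 3.11-fold, TMEM158 3.02-fold and MECOM 2.66-fold. PIM1 rose as well (adjusted p = 1.56e-10), from a group in which its probe was detected on 1 of 4 arrays, with a log2 change between 0.732 and 1.89 over the alternatives. The forkhead genes FOXA3 (2.19-fold) and FOXA2 (1.86-fold) rose while FOXA1 fell by 0.76. ADAM19 fell by 1.97 (adjusted p = 3.08e-10, lower in 4 of 4 arrays), SPDEF fell by 1.93, NMUR2 fell by 1.86, BDNF fell by 1.62, CHST4 fell by 1.62, PLAUR fell by 1.61 and MMP7 fell by 1.53. DKK1 fell by 2.21 on the probe used, with its other probe at -0.36 and not called. Without background correction the changes were smaller, with rises of 2.46-fold for MB21D2, 2.35-fold for TNFRSF1B, 2.16-fold for LYN, 2-fold for NDRG1, 1.68-fold for FOXA3 and 1.66-fold for TMEM158 and falls of 0.914 for SPDEF, 0.729 for CHST4, 0.687 for CXCL1, 0.626 for BDNF, 0.55 for EREG and 0.529 for CXCL8.

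A total of 1052 genes rose and 1062 fell, with 37 and 72 of them at or beyond 2-fold, and the median size of a called change was 0.462 on the log2 scale. Arrays with doxycycline held fewer beads, and with the mean number of beads as a covariate, added after the data had been seen, 263 rose and 406 fell, with wider errors and the sign of all 2114 kept. The groups did not overlap for 1735 of the 2114 genes, and for 16.4% of all features tested. Camera called 7 of 23 lists, 5 of which held with an estimated correlation. Antigen presentation genes fell in 10 of 23 with 1 higher (15 and 1 adjusted over the list alone), including HLA-DPA1 (fell by 1.26), HLA-DMB (fell by 1.08) and CD74 (fell by 0.96). Interferon-gamma response genes fell in 11 of 29 with 1 higher (13 and 1 adjusted over the list alone), including IDO1 (fell by 1.15), UBD (fell by 0.90) and GBP5 (fell by 0.73). Insulin and growth factor signalling genes fell in 10 of 23 with 2 higher (10 and 2 adjusted over the list alone), with EREG falling by 1.31. TGF-beta and BMP signalling genes fell in 5 of 15 with 1 higher (6 and 1 adjusted over the list alone), with BMP4 (fell by 1.43) and TGFBI (fell by 0.89). Junction and keratin genes fell in 7 of 21 with 2 higher (9 and 3 adjusted over the list alone), with CLDN1 (fell by 0.97), CLDN3 (fell by 0.88) and CLDN12 (fell by 0.70). The stem cell and Wnt target list was called downward with 5 of 15 lower and 3 higher (6 and 4 adjusted over the list alone), including AXIN2 (fell by 1.27) and CD44 (fell by 0.92), but adjusted p = 0.454 with an estimated correlation. The integrated stress response list was called upward with 5 of 21 higher and 1 lower (5 and 1 adjusted over the list alone), including GDF15 (1.52-fold) and ASNS (1.34-fold), but adjusted p = 0.191 with an estimated correlation. Among enterocyte genes CA2 rose 2.58-fold while KRT20 fell by 1.20 and CEACAM1 fell by 1.06, and MUC13 rose 2.13-fold. CXCL1 fell by 1.43, ADM fell by 1.27 and CXCL8 fell by 0.90.

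The fourth comparison asks what doxycycline changed in cells given TNF. BNIP5 rose 7.67-fold (log2 fold change 2.94, SE 0.12, adjusted p = 1.66e-11, higher in 4 of 4 arrays), LXN 7.32-fold, MB21D2 4.59-fold, FOXA3 3.98-fold, FOXA2 3.55-fold, TNFRSF1B 3.44-fold, ZNF296 3.37-fold and FAM43A 3.37-fold. ADAM19 fell by 2.12 (adjusted p = 1.25e-10, lower in 4 of 4 arrays), MMP7 fell by 2.02, BHLHE41 fell by 1.93, PLAU fell by 1.84, NMUR2 fell by 1.79, PTGS2 fell by 1.78 and IL17C fell by 1.72. DKK1 fell by 1.73 on the probe used, with its other probe at -0.07 and not called. SGK1 and CXCL6 each fell by 1.22, CXCL8 fell by 0.97, BIRC3 fell by 0.91, TNF fell by 0.83 and TNFAIP3 fell by 0.71, whereas FOS rose 2.28-fold. Without background correction BNIP5 rose 2.97-fold, MB21D2 2.14-fold, TNFRSF1B 2.22-fold FAM43A 1.69-fold and FOS 1.55-fold, BHLHE41 fell by 1.2, PLAU fell by 1.15, and CXCL6 fell by 0.455.

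In all, 1308 genes rose and 1209 fell, with 42 and 89 at or beyond 2-fold. The groups did not overlap for 2242 of the 2517, and for 21.5% of all features tested. With the bead covariate 312 rose and 425 fell, and all 2517 kept their sign. Doxycycline raised 659 genes in both TNF states, against 87.8 for independent sets, and lowered 630, against 82; the fold changes correlated across genes with an r of 0.718 and a rho of 0.618. Camera called 8 of 23 lists, and 6 held with an estimated correlation. NF-kB targets fell in 16 of 29 and rose in 0 (20 and 1 adjusted over the list alone), and chemokines and cytokines fell in 12 of 26 and rose in 3 (15 and 3 adjusted over the list alone). Interferon-gamma response genes fell in 10 of 29 (13 lower and 1 higher adjusted over the list alone), with IDO1 (fell by 0.99), UBD (fell by 0.85) and CIITA (fell by 0.73), and antigen presentation genes in 12 of 23 with 1 higher (13 and 1 adjusted over the list alone), with HLA-DPA1 (fell by 1.34), HLA-DRA (fell by 0.88) and HLA-DMB (fell by 0.85). Insulin and growth factor signalling genes fell in 7 of 23 with 1 higher (8 and 2 adjusted over the list alone), with EREG falling by 0.98. Junction and keratin genes fell in 9 of 21 with 2 higher (10 and 3 adjusted over the list alone), with CLDN1 (fell by 0.96), CLDN12 (fell by 0.75) and KRT19 (fell by 0.69). GATA and endoderm transcription factors were called upward with 4 of 17 higher and 3 lower (5 and 3 adjusted over the list alone), ZFPM1 among the higher at 2.05-fold, but adjusted p = 0.0682 with an estimated correlation. The mitochondrial ribosome and proteostasis list was called upward with 4 of 24 higher (4 adjusted over the list alone), MRPL15 among them at 1.5-fold, but adjusted p = 0.0682 with an estimated correlation. SPDEF fell by 1.56 and KRT20 fell by 0.93, while GDF15 rose 2.52-fold, MUC13 2.26-fold and CA2 2.17-fold. Without background correction ZFPM1 rose 1.57-fold, SPDEF fell by 0.727, EREG fell by 0.532 and CIITA fell by 0.38.

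**Figure D2:**
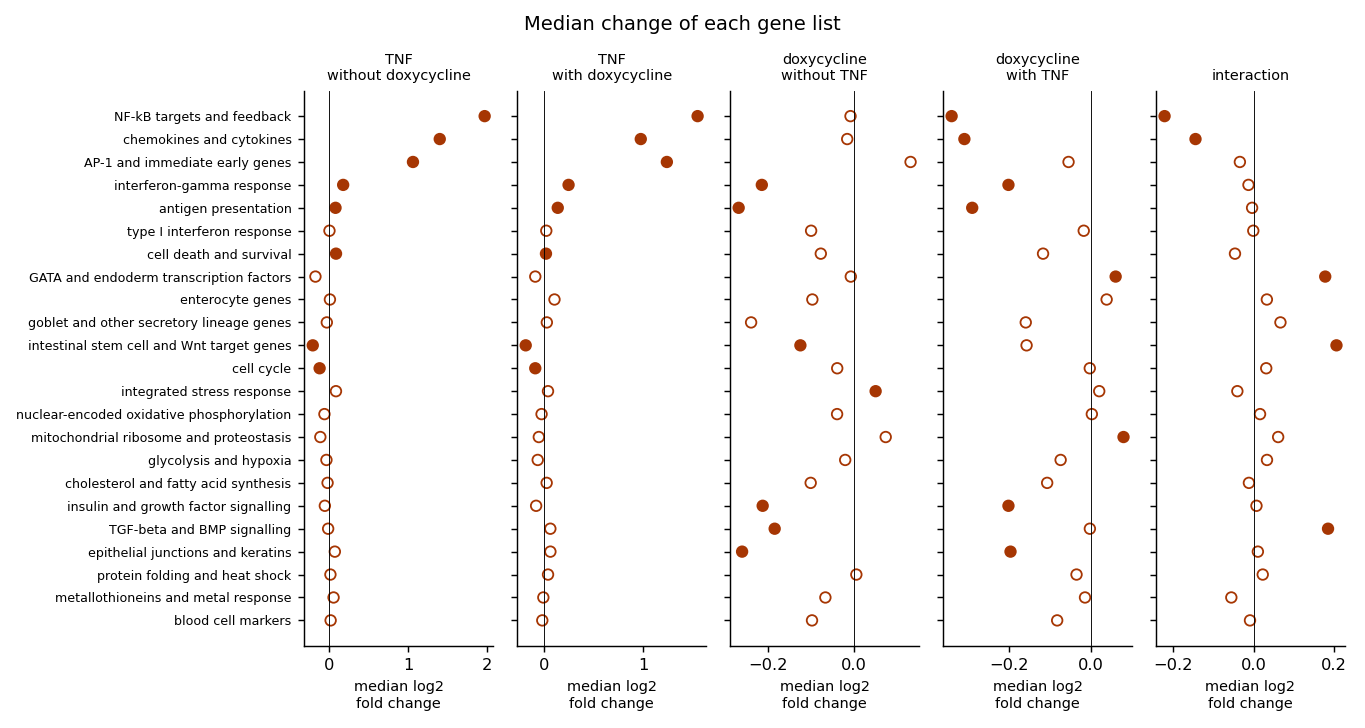
Median log2 fold change of the measured members of each list in the 5 comparisons, each panel with its own scale. Filled points passed camera at the preset correlation, open points did not; NF-kB targets had medians of 1.97 and 1.55 with TNF and -0.22 in the interaction.

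The interaction asks whether the response to TNF differed between cells with and without doxycycline. PLPP3 rose by 1.90 on the log2 scale without doxycycline, while its change with doxycycline, 0.25, did not pass the test (difference -1.65, adjusted p = 1.18e-06). The differences were -1.32 for TNFRSF6B, -1.30 for PTGS2 and -0.72 for PPP1R15A. The interaction was also called downward for PLAU, CXCL6, COXFA4L3, SERPINA3, LTB, CYP4B1, TNFAIP3 and TNF, and upward for BNIP5, FAM43A and BDNF. The probe of each of these was detected on at most 1 array in at least 1 of the 4 groups, so the difference between its responses has no exact size. In TNF-treated cells, where PLAU was detected on all arrays, it fell by 1.84 with doxycycline and all 4 arrays with doxycycline lay below the 4 without. FOS fell by 0.56 without doxycycline and rose by 0.35 with it (difference 0.91, adjusted p = 0.000956). FOXA2 (difference 0.93) and FOXA3 (0.86) rose with TNF only in cells with doxycycline, by 0.68 and 0.86. ZNF296 fell by 1.38 and 0.44, with a difference of 0.94, and FOXQ1 (0.79) fell by 0.53 without doxycycline. ID1 fell by 1.17 with TNF without doxycycline, with a difference of 1.32; the other probes of ID1 and BDNF were not called in the interaction (0.44 and 0.46).

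The interaction passed the test for 70 genes, 28 higher and 42 lower. The count depended on the processing, with 73 lower in the authors' values, 72 lower with an offset of 50, and 45 higher and 79 lower without background correction, where the differences of TNFRSF6B, ZNF296 and FOS were -0.821, 0.543 and 0.477. Of the 42 lower with the main processing, 26 rose with TNF in both states and 14 rose only without doxycycline, and 30 were lower with doxycycline only in TNF-treated cells, which the interaction itself tests. Among the 12115 features detected on at least 2 arrays of every group, a filter added after the data had been seen, 27 were higher and 29 lower. Camera called 5 of 23 lists. NF-kB targets were lower in 4 of 29 genes (10 adjusted over the list alone; camera adjusted p = 3.15e-12) and chemokines and cytokines in 5 of 26 (7 adjusted over the list alone; 1.14e-07), so most members of both did not pass. Among features detected in every group these counts were 3 of 25 (camera adjusted p = 1.31e-08) and 1 of 18 (camera adjusted p = 0.00522). With an estimated correlation camera gave these lists an adjusted p = 0.000364 and 0.0238 there. GATA and endoderm transcription factors were higher in 2 of 17 (5 adjusted over the list alone; adjusted p = 0.0104 with an estimated correlation) and TGF-beta and BMP signalling genes in 2 of 15 (4 adjusted over the list alone; adjusted p = 0.0111 with an estimated correlation). Stem cell and Wnt target genes were called upward with 0 of 15 past the test alone (2 higher and 1 lower adjusted over the list alone), but adjusted p = 0.476 with an estimated correlation.

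**Figure D3:**
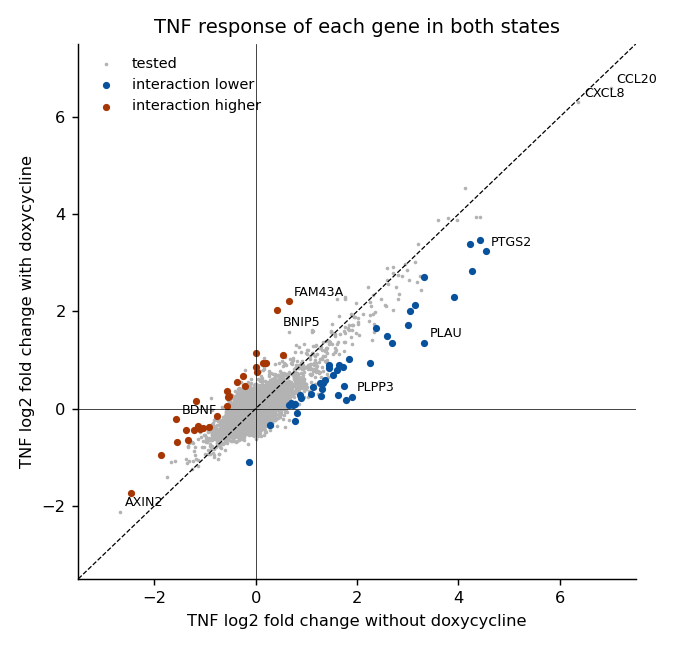
TNF log2 fold change of each tested gene with doxycycline against that without, with the line of equal response dashed. Genes with an interaction are coloured, 42 lower and 28 higher.

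Over all TNF-responsive genes, the response was compared in size. Of 1021 genes that rose with TNF in the mean of both states, among them CXCL8, PTGS2 and TNFAIP3, 660 (64.6%) rose less with doxycycline, with a median difference of -0.09 on the log2 scale (limma fry, adjusted p = 1.52e-07 over 4 such tests). The interaction passed for 40 of them towards a smaller and for 9 towards a larger response. Among the 172 with a mean rise of at least 2-fold, 75% rose less, with a median difference of -0.20 (adjusted p = 3.3e-08). Of 1222 genes that fell, 788 (64.5%) fell less, with a median signed difference of -0.07 (adjusted p = 3.8e-06), 14 of them called towards a smaller and 1 towards a larger response; of the 20 with a mean fall of at least 2-fold, 95% fell less (median -0.34, adjusted p = 5.4e-08).

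**Figure D4:**
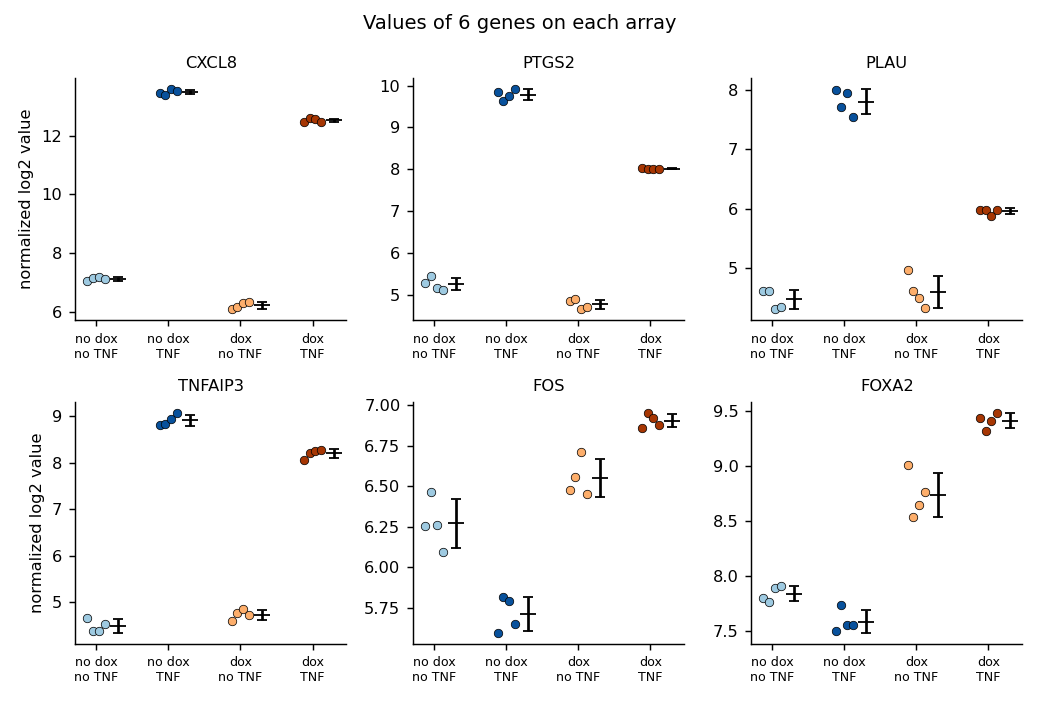
Normalized log2 values of CXCL8, PTGS2, PLAU, TNFAIP3, FOS and FOXA2 on each array, each panel with its own scale; points are arrays and bars mean ± SD of 4 arrays. PLAU and PTGS2 in TNF-treated cells were lower with doxycycline on 4 of 4 arrays, and FOS and FOXA2 were higher.

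GATA6 was measured by 1 probe, on chromosome 18 per the file, whose position in the transcript is not given in the sources used here. Its signal was 111 ± 5.39 (SD, n = 8) without doxycycline and 92.4 ± 6.86 (SD, n = 8) with it, and the exact two-sided permutation test gave p = 0.000155. All 8 arrays without doxycycline lay above the 8 with it, though the median signal of all probes was also lower with doxycycline (87.9 against 92.2). After normalization 7 of the 8 arrays with doxycycline lay below all without it, and the exact two-sided permutation test gave p = 0.000622. The probe was detected on 8 arrays without and on 4 with doxycycline, on 1 of 4 without TNF and on 3 of 4 with TNF, so the sizes of the changes are not exact. With the main processing the log2 fold change of GATA6 with doxycycline was -0.57 without TNF (SE 0.15, adjusted p = 0.0182, with 4 of 4 arrays under the mean of the other group and 3 under all its arrays) and -0.47 with TNF (SE 0.15, adjusted p = 0.0412, with 4 of 4 arrays under all of the other group). With the mean number of beads as a covariate the changes were -0.538 (SE 0.219) and -0.441 (SE 0.232), close to those without it but with wider errors, and both calls ended (adjusted p = 0.206 and 0.355). Over all alternatives the changes ranged from -0.738 to -0.188 and from -0.529 to -0.156, and the adjusted p ranged from 0.00107 to 0.206 and from 0.0113 to 0.355. GATA6 did not pass the test for TNF without doxycycline (0.01, adjusted p = 0.983), for TNF with doxycycline (0.10, adjusted p = 0.8) or for the interaction (0.09, adjusted p = 0.969).

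**Figure D5:**
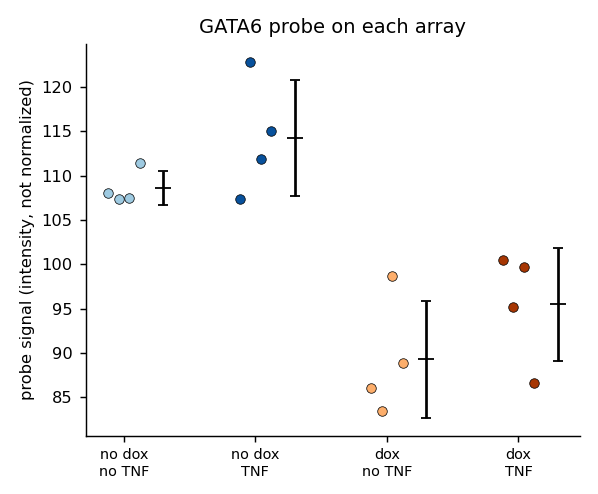
Signal of the GATA6 probe on each array by group, as an intensity that is not normalized, with mean ± SD of 4 arrays. The 8 arrays with doxycycline lie between 83.5 and 100.5 and the 8 without between 107.3 and 122.8; the axis does not start at 0.

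Several lists were not called by camera in any comparison. Ordered as TNF without and with doxycycline, doxycycline without and with TNF and the interaction, the adjusted p was 0.435, 0.315, 0.576, 0.627 and 0.975 for the type I interferon response, 0.466, 0.169, 0.491, 0.919 and 0.773 for enterocyte genes, and 0.398, 0.231, 0.107, 0.0535 and 0.975 for goblet and other secretory lineage genes. It was 0.293, 0.319, 0.576, 0.828 and 0.975 for nuclear-encoded oxidative phosphorylation, 0.979, 0.851, 0.61, 0.627 and 0.975 for glycolysis and hypoxia, and 0.376, 0.211, 0.107, 0.335 and 0.773 for cholesterol and fatty acid synthesis. For protein folding and heat shock it was 0.293, 0.198, 0.61, 0.681 and 0.975, for metallothioneins and metal response 0.293, 0.856, 0.61, 0.96 and 0.773, and for blood cell markers 0.979, 0.865, 0.434, 0.405 and 0.975. Of the fibroblast markers 3 were measured and the list was not tested; LUM rose with doxycycline without TNF (adjusted p = 0.00631) and with TNF (adjusted p = 0.000138), from groups without a detected array. Over the alternatives its log2 change lay between 0.187 and 0.554 and between 0.254 and 0.819, and both calls ended with the bead covariate (0.322, adjusted p = 0.266, and 0.542, adjusted p = 0.057). In 22 of the 115 list tests the median, the mean and the direction of camera differed in sign, 0 of them called; in the GATA and endoderm list with TNF and doxycycline the median was -0.09, the mean 0.12 and the direction upward.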

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

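The splits of the arrays, the tests of a ceiling, of the quantile step, of the bead numbers of single arrays, of drug effects and of the GATA6 probe were chosen only after the result was seen.

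The values of the named genes and the median signal, probes detected and mean beads of the arrays were searched for single arrays apart. In 19 of 456 groups of values, all of named genes, 1 array stood apart from the other 3 of its group. The criterion was a gap to the nearest array, as a share of the group's range, above Dixon's 95% critical value. Chance alone gives about 1 in 20, or 22.8, so these count as no pattern. The gap was 0.895 of the range for BMP4, 0.937 for BNIP5, 0.856 for CD44 and 0.9 for PRR15L, all in NoGATA6L_PlusTNF replicate 1, and 0.836 for CLDN12 and 0.916 for SLC25A24 in NoGATA6L_PlusTNF replicate 3. It was 0.833 for CDKN1A, 0.989 for HLA-DMB and 0.841 for MB21D2 in PlusGATA6L_NoTNF replicate 4, 0.924 for CEBPA in replicate 2 and 0.977 for FOSB in replicate 1 of that group. In NoGATA6L_NoTNF it was 0.851 for DUSP5 and 0.857 for ELF3 in replicate 4, 0.845 for CYP4B1 in replicate 1 and 0.86 for HLA-DPA1 in replicate 2. In PlusGATA6L_PlusTNF it was 0.906 for GATA6 and 0.849 for ZFPM1 in replicate 4, 0.909 for PLAU in replicate 3 and 0.838 for UBD in replicate 1.

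The TNF response of 26 named genes differed between cells with and without doxycycline by the interaction test. The response with doxycycline minus that without, on the log2 scale, was -1.97 for PLAU, -1.65 for PLPP3, -1.35 for CXCL6, -1.34 for COXFA4L3, -1.32 for TNFRSF6B, -1.3 for PTGS2, -1.28 for SERPINA3, -1.08 for LTB, -1.05 for CYP4B1, -0.955 for TNFAIP3, -0.826 for TNF, -0.716 for PPP1R15A, -0.61 for NFKBIA and -0.581 for PFKFB3. It was 1.61 for BNIP5, 1.56 for FAM43A, 1.35 for BDNF, 1.32 for ID1, 0.944 for ZNF296, 0.93 for FOXA2, 0.912 for FOS, 0.86 for FOXA3, 0.791 for ID2, 0.785 for FOXQ1, 0.769 for TXNIP and 0.727 for GDF15. The probes of PLAU, CXCL6, COXFA4L3, SERPINA3, LTB, CYP4B1, TNFAIP3, TNF, BNIP5, FAM43A and BDNF were detected on at most 1 array in at least 1 group, so their values are not exact differences. Other probes of BDNF (0.46), ID1 (0.44) and ID2 (0.42) had the same sign and were not called, and that of PFKFB3 gave 0.04. Of the 30 alternatives run for each, the adjusted p of NFKBIA ranged from 0.000299 to 0.2 and missed the threshold in 8, that of PFKFB3 from 0.00367 to 0.693 in 18, that of ID2 from 0.00192 to 0.609 in 6 and that of GDF15 from 0.000492 to 0.0583 in 5.

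Few other groupings of the same arrays gave as many called genes. For the 4 comparisons of TNF or doxycycline this argues against a chance division of these arrays, with 1 of 35 the smallest share that 35 splits can give. The splits cannot exclude a batch or culture difference that follows the groups, since the origin of the replicates is not given. For TNF without doxycycline 1 of the 35 splits gave 1522 genes, the real one, and the highest other gave 1. For TNF with doxycycline 1 of 35 gave 1076 and the highest other 1, for doxycycline without TNF 1 of 35 gave 2114 and the highest other 49, and for doxycycline with TNF 1 of 35 gave 2517 and the highest other 0. For the interaction 3 of 100 drawn splits gave at least the real 70 genes. The other 2 gave 1332 and 4266, and they exchanged the doxycycline labels of 3 or 4 arrays only among TNF-treated cells. They turn the doxycycline effect into an interaction, a structure of the samples. The drawn splits exchange doxycycline labels within each TNF state, which also moves the doxycycline effect into the spread within groups. Few calls can then arise whether or not an interaction exists. These splits therefore cannot show whether the interaction calls came by chance.

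The first pattern weighed is the smaller TNF response with doxycycline, with median differences of -0.0882 for genes that rose and -0.0693 for genes that fell. A ceiling of bright probes would need risers to start higher with doxycycline and end level, but their median doxycycline effect was -0.0407 without TNF and -0.129 with TNF (fry adjusted p = 1.4e-11), so they ended lower. Among features detected on at least 2 arrays of every group, 64.1% of 939 risers responded less (median -0.0778, fry adjusted p = 5.32e-06). There 63.7% of 1260 genes that fell did so (median -0.0631, fry adjusted p = 9.97e-06). Compression of dim values by the background step or offset was not tested separately and stays open. Of normalization between arrays, a share of 60% or more of risers with a smaller response under 75th percentile scaling was set in advance as evidence against it. The share was 60.6% (standard error 1.56), which clears that bound by less than its error, so a contribution of normalization stays open. That error is binomial over 984 genes, which are not independent, and the error between arrays was not measured. The quantile step as the whole cause is argued against, since with 75th percentile scaling the response remained smaller for risers (median -0.0665, fry adjusted p = 0.00272) and for genes that fell (median -0.111, fry adjusted p = 0.000191). A drug effect of doxycycline apart from the transgene cannot be told apart from GATA6L, since no cells without the cassette were among the arrays, and the 64.6% of risers that responded less may come from either. A dampened TNF response through GATA6L remains a hypothesis on the same footing.

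The second pattern is the many small changes with doxycycline, with 27.2% of genes called in its mean effect. Of 16988 probes undetected on every array, 0.00589% were called in that effect. A share of 5% or more had been set in advance as what an array background following doxycycline would give. The values were quantile normalized without background correction, which removes a shift shared by all probes. The test therefore cannot show or exclude such a shift, and covers only background that differs between probes. Of the undetected probes 8.1% had an unadjusted p under 0.05, somewhat above the 5.51% for TNF. These probes carry little RNA signal, so a batch in culture or labelling would not show in them and stays open. Arrays with doxycycline held fewer beads, 20.6 ± 0.493 (SD, n = 8) against 21.7 ± 0.327 (exact permutation p = 0.000932). With the number of beads per array as a covariate, the number of genes called by doxycycline was 31.6% of that without the covariate in cells without TNF. In cells with TNF it was 29.3%, and under 50% in both had been set in advance as what this cause would give. That result was met but is not decisive, because bead number follows doxycycline. The standard errors grew 1.42 and 1.5 times, while the median gene kept 93.8% and 92.8% of its change and all 2114 and 2517 kept their sign. Bead numbers exchanged at random within groups also left a median of only 792 and 935 genes. As few genes as with the real bead numbers were left in 14 and 6 of 100 draws, with the real arrangement counted among the draws. Bead number and doxycycline cannot be told apart here. The same holds for a drug effect apart from the transgene; for the integrated stress response list, adjusted p = 0.191 with an estimated correlation without TNF, which neither shows nor excludes one.

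The third pattern is the lower GATA6 probe signal in arrays labelled as induced. Noise of a dim probe is argued against, since the exact permutation test of the normalized values gave p = 0.000622, with 7 of 8 arrays with doxycycline under all without it; the calls within each TNF state ended under several alternatives. Exchanged doxycycline labels would turn the log2 change of -0.518 in the mean doxycycline effect, which is not exact for a probe near background, into a rise, but no separate measure of the transgene is among the values, so this cannot be told apart from a probe outside the transgene. The table has 1 GATA6 probe with no position in the transcript given. If it reads only the cell's own transcript, a transgene made of the coding sequence may go unseen while the cell's own GATA6 falls. Every direction given for doxycycline rests on the labels.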

How the results depend on the processing

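The mean number of beads per array as a covariate and a filter to probes detected on at least 2 arrays of every group were added after the data had been seen. Of 5888 values of 192 gene results under the alternatives, 5825 kept their direction and side of the threshold, 63 kept their direction and lost the threshold, and 0 reversed. Their sizes depended on the processing. On the log2 scale 73 of the 192 moved by over 1.5 times in at least 1 alternative: 64 were smaller by that much without background correction, 46 with the authors' and the series values and 27 with an offset of 50, while 75th percentile scaling, leaving out an array and the bead covariate moved 0. The median size was 0.736 of the main one without background correction. The size of the TNF response kept its direction and call under every alternative, from -0.192 to -0.0569 for genes that rose and -0.195 to -0.0389 for genes that fell, the lower ends from genes chosen by TNF without doxycycline alone, which favours a smaller response. Counts not given here stayed within 1.5 times their value. Unless stated, the cause of a change was not tested.

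Genes lower in the interaction came to 73 with the authors' values, 73 with the series values, 79 without background correction and 72 with an offset of 50, and genes higher to 45 without background correction, against 42 and 28. With a 2-fold minimum, higher and lower genes were 202 and 40 for TNF without doxycycline, 156 and 15 with it, 37 and 72 for doxycycline without TNF, 42 and 89 with it, and 5 and 16 for the interaction, fewer by construction. The adjusted p under 0.01 likewise left 431 genes lower for TNF without doxycycline and 253 with it, 492 higher and 555 lower for doxycycline without TNF, 697 and 698 with it, and 12 and 26 for the interaction. The estimated correlation called 4 lists for TNF without and 5 with doxycycline. Fry, which does not compare a list with other genes, called 17 and 19 for TNF and 16 and 16 for doxycycline. With the bead covariate doxycycline raised 263 and lowered 406 genes without TNF, and 312 and 425 with TNF, with wider standard errors since bead number follows doxycycline.

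Without background correction the GATA6 change for doxycycline without TNF was -0.188, with the call kept. The GATA6 probe lost its call for doxycycline with TNF without background correction (-0.156, adjusted p = 0.0782) and without a detection filter (-0.471, adjusted p = 0.0823), and in both doxycycline comparisons with the bead covariate (-0.538 and -0.441). Its change for TNF without doxycycline, which passed no test, reversed to -0.00145 with that covariate.

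Leaving out each array in turn gave ranges of 675 to 778 genes higher and 598 to 750 lower for TNF without doxycycline, 537 to 618 and 364 to 501 with it, 756 to 1038 and 819 to 1059 for doxycycline without TNF, 988 to 1357 and 970 to 1239 with TNF, and 21 to 30 and 32 to 40 for the interaction. Lists called for TNF with doxycycline ranged from 5 to 8, with 5 without PlusGATA6L_NoTNF replicate 2 and without PlusGATA6L_PlusTNF replicate 4. For GATA6 the log2 change ranged from -0.738 to -0.46 for doxycycline without TNF and lost its call without NoGATA6L_NoTNF replicate 4 (-0.535), PlusGATA6L_NoTNF replicate 1 (-0.532) and replicate 2 (-0.46). With TNF it ranged from -0.529 to -0.352 and lost its call without NoGATA6L_PlusTNF replicate 1 (-0.476), replicate 2 (-0.381) or replicate 3 (-0.499), or PlusGATA6L_PlusTNF replicate 1 (-0.509), replicate 2 (-0.504) or replicate 4 (-0.352). The uncalled changes ranged from -0.0797 to 0.0683 for TNF without doxycycline, reversing without NoGATA6L_NoTNF replicate 1 (-0.00151) or 2 (-0.0282) and NoGATA6L_PlusTNF replicate 2, from -0.00136 to 0.277 for TNF with doxycycline and from -0.0118 to 0.266 for the interaction, both reversing without PlusGATA6L_NoTNF replicate 2.

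Replicate numbers did not pair the arrays: correlations of residuals between arrays of the same number lay between -0.101 and 0.0771, and between others from -0.0829 to 0.0839. With the number as a block, the response size was -0.0929 and -0.0714. A slide block was not run. The stricter filter left 9 gene values without a result and the filter on every group 29, and GATA6 in all 5 comparisons. Signal over background limits the dim genes: the GATA6 probe was detected on 4 of 8 arrays with doxycycline.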

Other observations

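All tests of this part were chosen only after the result was seen.

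Doxycycline may move TNF-responsive genes against the TNF response. Of 920 genes called in the mean effects of both treatments, 617 (67.1%) moved in opposite directions, with a correlation across genes, which are not independent replicates, of -0.293 (Spearman's rho -0.35). Over all 15664 genes the relation was weak (Pearson's r -0.131, Spearman's rho -0.0811). Over the 1021 genes that rose with TNF, the median mean doxycycline effect was -0.0863 (fry adjusted p = 2.04e-11), and over the 1222 that fell the signed median was -0.0456 (fry adjusted p = 1.24e-05). The mean doxycycline effect averages the effects without and with TNF, so this observation is not separate from the smaller TNF response. For the genes that rose, the medians were -0.0407 without TNF (fry adjusted p = 6.93e-07) and -0.129 with TNF (fry adjusted p = 1.4e-11). The 20 genes that fell by at least 2-fold did not show it, with 55% opposed (adjusted p = 0.231). The hypothesis was found and tested on the same arrays and needs other samples.

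Gene families were formed by the letters that open a symbol, with at least 10 measured members. Of 144 families tested in each effect, those past camera at both the preset and the estimated correlation are given. In the mean TNF effect, 16 of 23 HOX genes fell and 0 rose (median -0.358, camera adjusted p = 0.000964 with an estimated correlation), 85 of 292 ZNF genes fell and 6 rose (median -0.132), 5 of 28 MRPS genes fell (median -0.127), and 14 of 56 SNORA genes rose (median 0.128). With TNF 8 of 19 HLA genes rose (median 0.206), as did 10 of 11 CXCL genes (median 1.07). So did 10 of 37 IL genes (median 0.0603) and 5 of 17 DUSP genes (median 0.0482), and 0 genes of these families fell. In the mean doxycycline effect, 15 of 19 HLA genes fell (median -0.548, camera adjusted p = 0.00326 with an estimated correlation), 14 of 22 KRT genes fell (median -0.284), and 71 of 292 ZNF genes rose and 6 fell (median 0.0901). Without background correction the medians were smaller, -0.209 for HOX, -0.0534 for ZNF, -0.108 for MRPS and 0.0418 for SNORA with TNF, and -0.359 for HLA, -0.204 for KRT and 0.0336 for ZNF with doxycycline. Each median kept its sign with the authors' values, without background correction, with an offset of 50 and with 75th percentile scaling. Bead number follows doxycycline, so the doxycycline medians carry that limit.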
